A study of Mus musculus with 20 samples.

How the data were processed

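Libraries were prepared by SMART-Seq2 from RNA extracted with the RNeasy Micro kit, per the labels' protocols, from whole E13.5 hearts (4 knockout and 4 wild-type embryos) and from P3 atria and ventricles (3 knockout and 3 wild-type pups, each pup labelled as giving both tissues). Genotype, stage, tissue, animal, litter and replicate number were taken from the labels, and sex was not given there. The submitters' processing notes name bcl2fastq 2.2, STAR 2.5.1, DESeq2 and the genome build mm10, without role or order. The counting tool and the annotation release are not given in the sources used here.

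The authors deposited 1 table of 26440 genes by 20 libraries, whose values were read as a normalized signal on a linear scale. No label says how they were scaled. From the values, the median ratio of each library to the gene-wise geometric mean over 12693 genes above 0 in all libraries was 1.04 in all 20 libraries, so that the libraries had been brought to a common scale. The low values of many genes were multiples of 1 step per library, as counts divided by a factor per library would be. Among processed pseudogenes, TEC, snoRNA and miRNA genes, 99.7 to 99.8% of values up to 100 estimated counts were whole multiples within 0.001 reads, and over all genes 45.2 to 64.6%, the rest being fractional. The step gave the estimated total counts of 5138352 to 20669361 per library, and each total is an estimate. PCR reads without molecular identifiers are not independent molecules, so the depth covers counting error only. No sample column was left unused.

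Values were tested as log2(value + 1) in R 4.3.3 with limma 3.58.1. Genes with a value of at least 10 in at least 3 libraries were kept, which left 18125. One fit gave a mean to each of the 6 groups of stage, tissue and genotype, with 14 residual and 6.68 prior degrees of freedom and a variance trend on the mean level. The contrasts were knockout minus wild-type at E13.5, in P3 atria and in P3 ventricles, all tests were two-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. The difference of the knockout effect between ventricles and atria was tested by limma on each pup's ventricle minus atrium difference, and that between ventricles and E13.5 hearts as a contrast, where stage and dissection cannot be told apart. The variance trend of the within-pup fits first ran on the mean difference and was changed to the mean log2 level after its first output had been seen. This moved the count of differing genes at an unadjusted p under 0.05 from 589 to 469, left 0 called by limma, and moved the called chamber genes from 0 to 26.

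Gene lists, 38 of them, of cardiac, metabolic, stress, cell-type, neighbouring-tissue and sex-linked genes were written from general knowledge before the data were examined, as were the main tests, the rule for named genes and the other fits compared with them. Lists with at least 5 measured members were tested by camera in limma with a preset correlation of 0.01, and again with an estimated correlation and by fry. Members called were counted over all genes and adjusted over the list alone. Named genes were Creld1 and Creld2, up to 8 genes per direction with the largest fold change among called genes of at least median level with a proper symbol, not sex-linked, and with non-overlapping groups, where fewer than 3 genes were called in a direction the 5 with the smallest unadjusted p (values only), and 2 to 4 members with the smallest p of each list that passed or held a called gene. Fcrls and the genes added by the replicate block were named after their values were seen. A gene that the rule for list members selected is not reported here.

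Knockout and wild-type libraries of 1 replicate number shared a litter and a preparation date per the labels, so the numbers pair the samples; E13.5 replicates 2 and 3 share 1 litter, and E13.5 replicate 4 was prepared in 2018 and the other E13.5 replicates in 2016. Deviations from the group means correlated at 0.212 to 0.638 between same-numbered atrial libraries and at -0.411 to 0.225 between the others. In ventricles the same-numbered correlations were 0.0200 to 0.0658 and at E13.5 they were -0.0159 to 0.0159. The fit without the block was set as the main one beforehand because no source says that the authors used a block. The pairs are part of the sampling all the same. Without the block, offsets that paired libraries share stay in the spread. This matters most in atria, where limma called 4 genes higher and 1 lower without the block and 20 and 10 with it.

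The main fit, the within-pup test and camera with the preset correlation were run on simulated data before use. Genes were drawn independently there, without pairs, litters or correlated lists. Each gene had 1 spread in all groups, the median over the 6 groups, so the offset of the third atrial pair was absent. In the real atria a grouping other than by genotype called 1123 genes. The simulated atrial recovery and false calls therefore need not hold for the real atria. The 200 changed genes of each comparison were drawn from genes of at least median level. With 200 changed genes among 18125, limma recovered 35.8, 82.1 and 98.5% of 2-, 4- and 8-fold changes at E13.5, 22.4, 71.6 and 100% in atria and 11.9, 82.1 and 90.9% in ventricles, with 8, 9 and 7 false calls among 17885 unchanged genes. The remaining 40 genes formed the simulated list below. In the same simulated data 134, 132 and 127 genes differed between ventricles and atria by 2-, 4- and 8-fold. The within-pup test recovered 1.49, 21.2 and 52.8% of them, with 1 false call among 17729 unchanged genes. The simulated list, shifted by 1.5-fold, was called by camera in each comparison, and 0 of 37 unchanged lists were. Because these lists held no correlated genes, this cannot show how often camera falsely calls real lists. Estimated correlations of the real lists reached 0.49 with the replicate block.

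Coordinates and gene types came from the GENCODE annotation of the mm10 build supplied as the reference, in which 26401 of the 26440 identifiers were found with version numbers ignored (99.9%), 94.7% of them with the same symbol. Shares of signal were compared by exact permutation tests, two-sided, over all regroupings of the libraries and without regard to the pairs. Alternatives covered the filter, the pseudocount, the scaling, separate fits, blocks for replicate, litter and pup, library weights, robust variance, thresholds, an Xist covariate and leaving out each library in turn. Added after the data had been seen were voom weights, leaving out the third atrial pair, leaving out wild-type pup 2, removing mitochondrial transcripts, the replicate block with an estimated correlation, and the variance trend on the mean difference. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.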

Results

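Messenger RNA was profiled in 20 libraries from C57BL/6N mice, each made from the heart tissue of 1 animal. The libraries came either from mice in which Creld1 had been deleted in the myocardium under a cardiac myosin heavy chain driver, or from wild-type littermates. At the embryonic stage E13.5 whole hearts were taken from 8 embryos of 3 litters, 4 knockout and 4 wild-type. At postnatal day 3 (P3) atria and ventricles were taken separately from 6 pups of 3 litters, 3 knockout and 3 wild-type, and the labels give 2 libraries to each pup. The estimated total counts ranged from 5138352 to 20669361 per library, and 18357 to 23457 genes had a value above 0. The knockout library had the higher total in 3 of 4 pairs at E13.5, 3 of 3 in atria and 2 of 3 in ventricles. Exact permutation tests of the totals, which ignore the pairs, gave a two-sided p of 0.571, 0.5 and 0.2. Within-group pairs of libraries differed by 13.6 to 106 times the counting noise, and no library was identical to another.

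Creld1 encodes an endoplasmic reticulum membrane protein with epidermal growth factor-like domains and lies on chromosome 6 from 113483297 to 113493343 on the plus strand of mm10, with up to 10 exons in a transcript. In E13.5 hearts its normalized signal was 66.0, 92.2, 60.8 and 34.0 in wild-type replicates 1 to 4. In the libraries labelled E13.5 knockout it was 70.9, 7.48, 38.4 and 4.64, so that the library labelled knockout replicate 1 lay above its wild-type littermate. In P3 atria it was 105, 21.6 and 146 in wild-type and 23.1, 26.6 and 82.4 in knockout, and the library labelled atrial knockout replicate 2 lay above the wild-type library of the same litter. In P3 ventricles it was 62.2, 59.7 and 130 in wild-type and 19.9, 59.3 and 51.9 in knockout, and the highest knockout value lay just below the lowest wild-type value, both from replicate 2. By the labels, knockout pup 2 thus had no clearly lower Creld1 than wild-type pup 2 in either tissue. The wild-type pup 2 libraries are themselves in doubt, since they differed in sex-linked transcripts and the atrial one held ventricular transcripts. In atrial replicate 2, 1 estimated count equalled a signal of 2.21 in wild-type and 0.997 in knockout, so both values rest on few reads. Creld1 means were 63.2 ± 23.8 (SD, n = 4) and 30.3 ± 31.0 (SD, n = 4) at E13.5, with a log2 fold change of -1.66. They were 91.0 ± 63.5 (SD, n = 3) and 44.1 ± 33.3 (SD, n = 3) in atria, a log2 fold change of -0.89, and 83.8 ± 39.7 (SD, n = 3) and 43.7 ± 20.9 (SD, n = 3) in ventricles, a log2 fold change of -0.97. None of the 3 differences passed limma's test, each with an adjusted p of 1. The labels do not say which exons were deleted, and heart cells other than myocardium keep the gene, so a remaining signal does not by itself contradict a label. The direction in all 3 comparisons rests on the labels of these libraries, including the library labelled E13.5 knockout replicate 1 and both libraries labelled knockout pup 2, among them the library labelled atrial knockout replicate 2. Creld2, the paralog, which encodes a stress-inducible endoplasmic reticulum protein, was 278 ± 52.6 (SD, n = 3) in wild-type and 474 ± 136 (SD, n = 3) in knockout atria, a log2 fold change of 0.74 that did not pass limma's test (adjusted p = 0.929). Its log2 fold change was 0.56 in ventricles (0.26 without ventricular knockout replicate 3) and -0.32 at E13.5 (-0.07 without E13.5 knockout replicate 1). The atrial log2 fold change of Creld1 was -0.36 without atrial wild-type replicate 3.

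**Figure D1:**
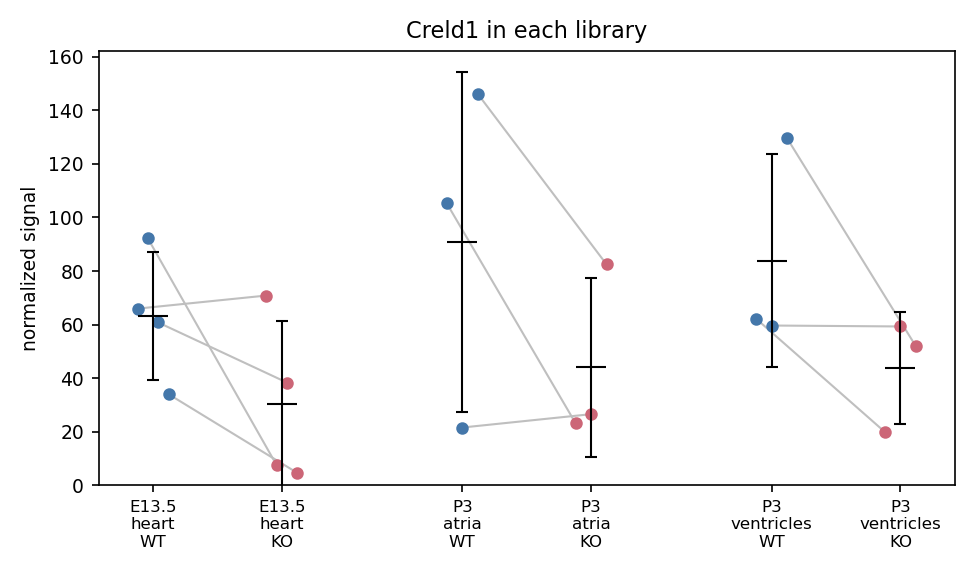
Creld1 normalized signal (y axis) in each library, by stage, tissue and genotype, with points for libraries, bars for the mean ± SD and grey lines joining the knockout and wild-type library of the same replicate number. The library labelled E13.5 knockout replicate 1 sits at 70.9 beside 66.0 in its littermate, and the library labelled atrial knockout replicate 2 at 26.6 beside 21.6.

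The tissue labels were checked in the 3 wild-type pups with genes of each chamber. Sln, which encodes the atrial calcium pump regulator sarcolipin, was lower in ventricles by a log2 difference of -5.91, the atrial light chain gene Myl7 by -5.18 and the atrial growth factor gene Bmp10 by -7.27. The ventricular light chain gene Myl2 was higher in ventricles by 7.89, and Myl3 by 3.53. Of 19 atrial genes 16 were called on the atrial side, and of 20 ventricular genes 10 on the ventricular side, by limma on within-pup differences, adjusted over the 2 chamber lists alone, and 0 on the other side. The count of 26 rests on a variance trend chosen after a first result was seen, and with the trend first used it was 0. Without wild-type pup 1 it was 17. In the atrial library of wild-type pup 2, Myl2 stood at 9242 beside at most 40.8 in the other wild-type atria, so this library held ventricular transcripts. The libraries of this pup also differed in sex-linked transcripts: Xist, the transcript of the inactive X, was 2876 in its atria and 74.9 in its ventricles. Y-linked transcripts exceeded Xist in 1 of 4 wild-type and 3 of 4 knockout libraries at E13.5, so sex was unevenly spread over the genotypes there.

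The E13.5 comparison asked what loss of Creld1 in the myocardium does to the forming heart. No gene passed limma's test in either direction over 18125 genes (0 higher and 0 lower, smallest adjusted p = 0.119). An unadjusted p under 0.05 was found for 747 genes, 433 higher and 314 lower, where 906 would be expected if limma's p-values were exact. Other groupings of the same libraries gave at most 893. The groups did not overlap in 2.54% of genes. Among genes given as values only, the mitotic kinesin gene Kif11 was 184 ± 123 (SD, n = 4) in wild-type and 485 ± 53.8 (SD, n = 4) in knockout, a log2 fold change of 1.67. Pkhd1l1, which encodes a large membrane receptor-like protein, was 40.1 ± 8.76 (SD, n = 4) and 235 ± 123 (SD, n = 4), a log2 fold change of 2.37. Prkag2, a regulatory subunit gene of AMP-activated kinase, the receptor kinase gene Grk3 and the single-strand DNA binding protein gene Nabp1 had log2 fold changes of 1.71, 1.60 and 1.59. On the lower side the helicase gene Dhx30 was 639 ± 180 (SD, n = 4) and 272 ± 74.7 (SD, n = 4), a log2 fold change of -1.24. Tprkb, a gene of the tRNA-modifying KEOPS complex, had -2.41, the proteasome-interacting protein gene Fam192a -2.86, the DNA repair gene Xpa -1.23 and the zinc finger gene Zfp704 -0.91. All 10 of these genes kept the 4 knockout libraries on 1 side of the 4 wild-type libraries, and limma's adjusted p was 0.664 to 0.704. They were picked for their small unadjusted p, which favours such separation. Without E13.5 wild-type replicate 3 limma called 1 gene higher, and without E13.5 wild-type replicate 4 it called 1 lower.

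Of 38 gene lists camera called 2 at E13.5. Fibroblast markers were higher, with 14 of 15 members positive and a median log2 fold change of 0.32 (camera adjusted p = 0.00179, and adjusted p = 0.099 with an estimated correlation). Ddr2, a collagen receptor gene, was 100 ± 47.0 (SD, n = 4) and 233 ± 119 (SD, n = 4), and Mfap5, Dpt and Col3a1, which encode matrix proteins, had log2 fold changes of 1.43, 0.43 and 0.32. Without E13.5 wild-type replicate 1 Mfap5 had 0.41 and Dpt 0.08. Cytosolic ribosomal protein genes were lower, with 49 of 52 members negative and a median of -0.19, led by Rpl8 (-0.34), Rps27 (-0.35), Rps18 (-0.30) and Rpl28 (-0.36). Their camera adjusted p was 0.00156, and adjusted p = 0.952 with an estimated correlation. No member of any list was called over all genes by limma. Adjusted over the list alone, 1 fibroblast marker (Ddr2), 1 cell cycle gene and 1 acetylcholine receptor gene were higher, 1 replication-dependent histone gene was lower, and the p53 list had 1 on each side. Without E13.5 knockout replicate 2 the fibroblast list had a camera adjusted p of 0.14, and without E13.5 wild-type replicate 1 the ribosomal list had a median of -0.10 and a camera adjusted p of 0.255. Without E13.5 wild-type replicate 2 the ribosomal median was -0.28. The medians of the atrial and ventricular chamber lists lay near 0 and changed sign with the scaling. Of the lists not called at E13.5, calcineurin, calcium handling, ion channels, glycolysis, erythroid, macrophage, chaperone, cholesterol and atrial chamber genes had medians, means and tests that differed in sign.

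The atrial comparison asked the same question in the upper chambers after birth. Limma called 4 genes higher and 1 lower. Mest, an imprinted gene of a hydrolase-like protein on chromosome 6 from 30723547 to 30748465, rose from 2572 ± 378 (SD, n = 3) to 11702 ± 2064 (SD, n = 3), a log2 fold change of 2.18 with an SE of 0.24 (limma adjusted p = 1.62e-04). Nppb, the gene of B-type natriuretic peptide on chromosome 4 from 147985788 to 147987205, rose from 360 ± 235 (SD, n = 3) to 3573 ± 1368 (SD, n = 3), a log2 fold change of 3.44 with an SE of 0.49 (limma adjusted p = 0.00656). Casq1, the gene of skeletal muscle calsequestrin on chromosome 1 from 172209894 to 172219868, rose from 53.7 ± 26.6 (SD, n = 3) to 864 ± 664 (SD, n = 3), a log2 fold change of 3.85 with an SE of 0.62 (limma adjusted p = 0.0187). Birc5, the gene of the mitotic protein survivin on chromosome 11 from 117849251 to 117855743, rose from 245 ± 21.7 (SD, n = 3) to 708 ± 168 (SD, n = 3), higher in 3 of 3 pairs with an SE of 0.26 for its log2 fold change (limma adjusted p = 0.0374). Lum, the gene of the collagen-binding proteoglycan lumican on chromosome 10 from 97565128 to 97572703, fell from 2123 ± 668 (SD, n = 3) to 586 ± 131 (SD, n = 3), a log2 fold change of -1.82 with an SE of 0.28 (limma adjusted p = 0.0133). For all 5 genes the 3 knockout libraries lay on 1 side of the 3 wild-type libraries. Exons of Casq1 overlap Gm17224 and those of Mest overlap Copg2 on the opposite strand, and no source used here says that the counting used strand, so reads of these pairs are uncertain.

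Below the threshold, Mb, the myoglobin gene, was 2994 ± 1396 (SD, n = 3) and 676 ± 591 (SD, n = 3), a log2 fold change of -2.35, and Dcn, the decorin gene, 5107 ± 621 (SD, n = 3) and 1884 ± 406 (SD, n = 3), a log2 fold change of -1.45. Emilin2, an elastic fibre gene, and Pcdh17, a protocadherin gene, had log2 fold changes of -1.89 and -2.21. Across all genes 964 had an unadjusted p under 0.05, 534 higher and 430 lower, where 906 would be expected if limma's p-values were exact. Other groupings of the same libraries gave up to 4351, and at most 382 where every pair was parted, so 906 is no fair chance level here. The groups did not overlap in 7.91% of genes, where chance gives 10%. With the replicate number as a block limma called 20 genes higher and 10 lower, among them all 5. Among the genes added by the block were Mb (limma adjusted p = 0.00758), Dcn (0.0127), the actin gene Acta2 (log2 fold change 1.66), the sarcoplasmic calcium pump gene Atp2a2 (-0.87), Nppa (1.45) and the endoplasmic reticulum stress gene Manf (1.38). It also added the globin genes Hba-a1 (1.92), Hba-a2 (1.78) and Hbb-bs (1.59) and the mitochondrially encoded mt-Rnr2 (-0.997) and mt-Nd4l (-0.94). Mest kept its call when any 1 of the 20 libraries was left out. Nppb had a limma adjusted p of 0.0571 without atrial knockout replicate 2 and 0.0504 without atrial wild-type replicate 1. Casq1 had 0.0571 and 0.096 without atrial knockout replicates 2 and 3, and 0.143 and 0.0741 without wild-type replicates 1 and 2. Lum had 0.0889 without knockout replicate 1, and 0.125 and 0.0741 without wild-type replicates 1 and 2. Birc5 lost its call when any 1 of 14 libraries was left out, with a limma adjusted p of up to 0.276 (without atrial knockout replicate 2). The counts of higher genes were 1, 1, 2 and 11 without atrial knockout replicate 2 and wild-type replicates 1, 2 and 3. The counts of lower genes were 0, 4, 0 and 5 without atrial knockout replicates 1 and 3 and wild-type replicates 2 and 3. At an unadjusted p under 0.05 there were 1492 genes without atrial knockout replicate 3 and 1973 without atrial wild-type replicate 3. With log2 Xist as a covariate only Mest and Nppb were called, and Casq1, Birc5 and Lum had a limma adjusted p of 0.0525, 0.0626 and 0.0525. The fits that follow were chosen after the data were seen. Without wild-type pup 2 Casq1, Birc5 and Lum had a limma adjusted p of 0.108, 0.166 and 0.135. Without the third atrial pair Casq1 had 0.0672, and with voom weights Casq1 had 0.295 and Birc5 0.0522 by limma. Birc5 was also not called with no filter (limma adjusted p = 0.0540), which had been chosen before. When each stage and tissue was fitted alone, limma called 0 genes in atria, with 572 at an unadjusted p under 0.05. The 5 calls thus depend on the spread shared over the 6 groups. In ventricles the same separate fits raised that count from 707 to 1065.

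**Figure D2:**
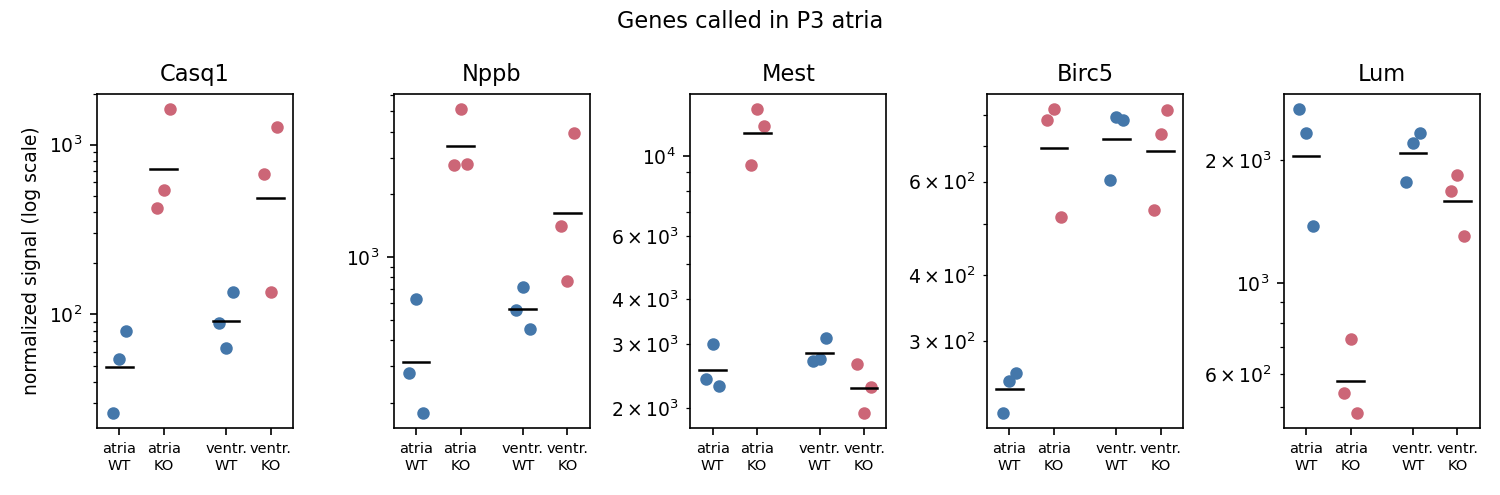
Normalized signal (y axis, log scale) of the 5 genes called in P3 atria, in P3 atria and ventricles (x axis), with points for the 3 wild-type (blue) and 3 knockout (red) libraries of each tissue and lines for the geometric mean. In atria Mest, Nppb, Casq1 and Birc5 lie higher and Lum lower in every knockout library than in every wild-type library.

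Camera called 17 of 38 lists in the atria, 11 higher and 6 lower, and 5 of them held with an estimated correlation: cell cycle, ion channels, fatty acid oxidation, endoplasmic reticulum chaperones and fibroblast markers. Of these 5, only fatty acid oxidation was lost when the replicate block was added to the estimated correlation (camera adjusted p = 0.146). The number of called lists was 11, 10 and 11 without atrial knockout replicate 3 and wild-type replicates 1 and 2. In the cell cycle list 48 of 51 members were positive with a median log2 fold change of 0.64 (camera adjusted p = 2.44e-14). Besides Birc5, the ubiquitin-conjugating enzyme gene Ube2c was 217 ± 99.4 (SD, n = 3) and 507 ± 41.8 (SD, n = 3), and the cyclin gene Ccnb2 and the cytokinesis gene Ect2 had log2 fold changes of 1.11 and 1.08. Ion channel, gap junction and conduction genes were negative in 22 of 24 members with a median of -0.96 (camera adjusted p = 7.6e-06). The calcium channel gene Cacna1d was 84.6 ± 18.2 (SD, n = 3) and 25.9 ± 12.1 (SD, n = 3), and the conduction system transcription factor gene Tbx3 had a log2 fold change of -2.12 (-0.86 without atrial knockout replicate 1). Fatty acid oxidation genes were negative in 27 of 33 members with a median of -0.51 (camera adjusted p = 1.51e-06), including the dehydrogenase gene Hadh (-0.78), the fatty acid binding protein gene Fabp3 (-0.95) and Hadhb (-0.56). Over its alternatives Fabp3 ranged from -1.62 to -0.51. Endoplasmic reticulum chaperone and unfolded protein response genes were positive in 26 of 31 members with a median of 0.52 (camera adjusted p = 1.75e-05). In this list Manf was 316 ± 62.3 (SD, n = 3) and 827 ± 194 (SD, n = 3), the chaperone gene Hspa5 had 0.55, Dnajc3 0.63 and Ero1lb -0.90. Fibroblast markers were negative in 11 of 15 members with a median of -0.58 (camera adjusted p = 1.75e-05), including Lum, Dcn, the periostin gene Postn (-0.83, and -0.39 without atrial knockout replicate 3) and the gelsolin gene Gsn (-0.82). Adjusted over the list alone, 2 cell cycle genes and 1 chaperone gene were higher and 2 fibroblast markers lower, beside 1 (Birc5), 0 and 1 (Lum) over all genes by limma. No ion channel or fatty acid oxidation gene passed limma's test, over all genes or adjusted over the list alone. Without atrial knockout replicate 3 the chaperone list's median was 0.29, and its camera call stayed.

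The other 12 atrial calls were lost with an estimated correlation. Ribosomal protein genes were positive in 51 of 52 members with a median of 0.65 (camera adjusted p = 4.32e-28, adjusted p = 0.0562 with an estimated correlation). Rpl14, Rps16, Rpl8 and Rps2 had log2 fold changes of 0.79, 0.98, 0.74 and 0.69, and 14 members were higher adjusted over the list alone beside 0 over all genes by limma. Without atrial wild-type replicate 3 this median was 0.30. Erythroid markers were positive in 12 of 15 members with a median of 1.34 (camera adjusted p = 5.71e-05, adjusted p = 0.155 with an estimated correlation), and 5 were higher adjusted over the list alone beside 0 over all genes by limma. The globin gene Hba-a1 was 2147 ± 427 (SD, n = 3) and 10571 ± 9851 (SD, n = 3), and the haem synthesis gene Alas2 had 1.92. With the replicate block Hba-a1 and Hba-a2 were called over all genes (limma adjusted p = 0.0425 for each). Without atrial wild-type replicate 2 the erythroid median was 0.84. Stress and hypertrophy genes were positive in 12 of 19 members with a median of 0.94 (camera adjusted p = 1.29e-04, adjusted p = 0.0796 with an estimated correlation), and 5 were higher adjusted over the list alone beside 1 (Nppb) over all genes by limma. The receptor gene Tnfrsf12a had 2.49, the matrix signalling gene Ctgf 1.60 and the small heat shock gene Hspb1 0.94. The stress median was 0.56 and 0.60 without atrial knockout replicates 2 and 3, and 0.52 without wild-type replicate 1 or 2. Heat shock and proteasome genes had a median of 0.30 (camera adjusted p = 0.00113, adjusted p = 0.112 with an estimated correlation), with Hsp90aa1 at 0.99 and Psma5 at 0.57, and were not called without atrial wild-type replicate 3 (adjusted p = 0.112).

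Mitochondrially encoded transcripts were negative in 15 of 15 members in the atria with a median of -0.78 (camera adjusted p = 1.94e-04, adjusted p = 0.448 with an estimated correlation), including mt-Co1 (-1.07) and mt-Nd4l (-0.94), which had -0.23 and -0.17 without atrial knockout replicate 3. Their median was 0.28 without atrial knockout replicate 3 (camera adjusted p = 0.345), -0.43 and -0.31 without wild-type replicates 1 and 2 (0.132 and 0.275), -1.20 and -1.37 without knockout replicates 1 and 2, and -1.53 without wild-type replicate 3. The third pair had a median log2 difference of -2.68 from the other atria for these transcripts. Leaving out 1 library of that pair keeps this offset in 1 genotype only. Ventricular chamber genes were lower with a median of -0.45 (camera adjusted p = 0.00202, adjusted p = 0.138 with an estimated correlation), including Mpped2 (-1.99, and -0.87 without atrial knockout replicate 2) and Kcnd2 (-2.67, and -1.18 without atrial knockout replicate 3), while Ankrd1 was 17537 ± 9381 (SD, n = 3) and 35775 ± 7723 (SD, n = 3). Kcnd2 was not higher in ventricles than in atria of wild-type pups, with a log2 difference of -0.25. The list median was -0.03 (camera adjusted p = 0.854) without wild-type replicate 2, the library that held ventricular transcripts, and -0.69 without wild-type replicate 3. Immediate early genes, among them Jun (-0.87) and Klf4 (-0.97), had a median of -0.51 (camera adjusted p = 0.022, adjusted p = 0.0796 with an estimated correlation), and 0.118, 0.0772 and 0.088 without knockout replicate 1 and wild-type replicates 1 and 2. Replication-dependent histones, among them Hist1h1c (1.06) and, against the list, Hist1h4h (-1.64, and -0.10 without atrial knockout replicate 2), had a median of 0.81 (camera adjusted p = 0.0307, adjusted p = 0.112 with an estimated correlation). Without knockout replicate 3 it was 0.50 (camera adjusted p = 0.345), and without wild-type replicates 1 and 2 the adjusted p was 0.132 and 0.0945. Collagen and matrix genes had a median of 0.31 with 34 of 55 members positive (camera adjusted p = 0.0326, adjusted p = 0.388 with an estimated correlation). Adjusted over the list alone 6 were higher, such as the crosslinking enzyme gene Lox (1.19), and 3 lower, beside 1 (Lum) over all genes by limma. The matrix median was 0.06 without knockout replicate 3 (camera adjusted p = 0.946), 0.13 without wild-type replicate 1 or 2 (0.5 and 0.0951) and 0.49 without wild-type replicate 3.

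Glycolysis, hypoxia and ATF4 genes were called by camera close to the threshold in the atria, with adjusted p = 0.0481, 0.0492 and 0.0481 and adjusted p = 0.584, 0.375 and 0.347 with an estimated correlation. The glycolytic genes Pgam1 and Pgk1 had log2 fold changes of 0.89 and 0.64, the hypoxia-responsive collagen hydroxylase gene P4ha1 1.22 and the serine synthesis gene Psat1 1.22. Over its alternatives Pgk1 ranged from 0.28 to 0.87. The 3 medians were 0.29, 0.19 and 0.33, and they were -0.24, -0.18 and -0.11 without atrial knockout replicate 3. Without wild-type replicate 1 they were 0.14, -0.00464 and 0.22 and without wild-type replicate 2 they were 0.07, 0.12 and 0.04, none of them called by camera. Without wild-type replicate 3 they were 0.63, 0.40 and 0.64, hypoxia not being called (camera adjusted p = 0.0528), and without knockout replicate 2 they were 0.59, 0.33 and 0.66. Without knockout replicate 1 the glycolysis and hypoxia medians were 0.50 and 0.41. Leaving out single E13.5 or ventricular libraries also ended these calls, with camera adjusted p up to 0.0614 (glycolysis, without E13.5 wild-type replicate 1). With the replicate block the ATF4 list was lost (camera adjusted p = 0.0527), and calcium handling (0.0287) and sarcomere genes (0.0227) were added, so that 18 lists were called. With the block and an estimated correlation together camera called 6 lists: cell cycle, ion channel, chaperone and fibroblast genes, erythroid markers (adjusted p = 0.0174) and mitochondrially encoded transcripts (0.0205). Fatty acid oxidation (0.146), calcium handling (0.146) and sarcomere genes (0.501) were not called by camera then. Nuclear-encoded oxidative phosphorylation genes were not called in the atria, and the sign of their median changed with the scaling. The calcineurin, p53, macrophage, acetylcholine receptor and lung lists, none of them called in the atria, had medians, means and tests that differed in sign. Among lists not called, adjusted over the list alone, calcium handling had 1 gene higher (Casq1) and 2 lower, endothelial markers 3 higher and 3 lower, smooth muscle markers 3 higher and 2 lower, and the calcineurin list 1 higher (Nppb). The third atrial pair differed from the other atria along the GC content of the transcripts, by 2.27 log2 units between the genes of highest and of lowest GC content, while the atrial knockout effect differed by 0.17 between them.

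The ventricular comparison asked the question in the pumping chambers of the same pups. No gene passed limma's test (0 higher and 0 lower, smallest adjusted p = 0.119). An unadjusted p under 0.05 was found for 707 genes, 361 higher and 346 lower, where 906 would be expected if limma's p-values were exact. Other groupings of the same libraries gave 483 to 673, so 906 is no fair chance level here. The groups did not overlap in 10.5% of genes, where chance gives 10%. Limma called 1 gene higher without E13.5 knockout replicate 1 or 3, atrial wild-type replicate 2 or ventricular wild-type replicate 2, and 1 lower without ventricular knockout replicate 2. With the replicate block limma called 2 genes higher. Nppa, the atrial natriuretic peptide gene on chromosome 4 from 148000722 to 148002079, was 2342 ± 2662 (SD, n = 3) and 15009 ± 14643 (SD, n = 3), higher in 3 of 3 pairs with a log2 fold change of 2.70 (limma adjusted p = 0.808, and 0.00121 with the block). Its exons overlap Gm13054 on the opposite strand. In wild-type pups Nppa was lower in ventricles than in atria by a log2 difference of -5.21. Atrial tissue in a ventricular library would therefore raise it, and such tissue was not tested for. The atrial chamber list had a median log2 fold change of 0.25 in ventricles and was not called by camera. Fcrls, an Fc receptor-like gene of macrophages, had a log2 fold change of 5.69 (limma adjusted p = 0.119, and 0.0223 with the block). Its level was not compared with the signal of 1 estimated count. Among genes given as values only, the DNA repair helicase gene Ercc6 had a log2 fold change of 3.09, and the Z-disc gene Pdlim3 was 447 ± 133 (SD, n = 3) and 1236 ± 426 (SD, n = 3). The protease gene Adamts8, the matrix gene Spon1 and the methionine synthase gene Mtr had log2 fold changes of 1.64, 1.18 and 1.66. On the lower side the coenzyme Q synthesis gene Pdss2 had -1.74, the calcium-binding protein gene Hrc -1.12, the centromere gene Cenpp -1.85, the integrin gene Itga6 -0.86 and the lipid kinase gene Pik3c3 -1.32.

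Camera called 7 of 38 lists in the ventricles, 5 higher and 2 lower, and 2 held with an estimated correlation: fatty acid oxidation and the stress and hypertrophy genes. Both were lost when the replicate block was added to the estimated correlation (camera adjusted p = 0.166 for each). Fatty acid oxidation genes were negative in 33 of 33 members with a median log2 fold change of -0.56 (camera adjusted p = 2.19e-10), and in 15 of them the groups did not overlap, where chance gives 10% of genes. Decr1, a reductase gene of unsaturated fatty acid breakdown, was 2792 ± 73.9 (SD, n = 3) and 1552 ± 250 (SD, n = 3). The dehydrogenase genes Acadm and Hadh and the thiolase gene Hadhb had log2 fold changes of -0.71, -0.78 and -0.72. Stress and hypertrophy genes were positive in 18 of 19 members with a median of 0.71 (camera adjusted p = 1.22e-08). Ankrd1, a stretch-responsive gene, was 9858 ± 1499 (SD, n = 3) and 31986 ± 19353 (SD, n = 3), Nppb 576 ± 136 (SD, n = 3) and 2033 ± 1668 (SD, n = 3), and Ctgf had 1.81. Adjusted over the list alone 4 stress genes were higher and 0 fatty acid oxidation genes lower, and over all genes limma called 0 in both.

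The remaining 5 ventricular calls were lost with an estimated correlation. Nuclear-encoded oxidative phosphorylation genes were negative in 56 of 57 members with a median of -0.26 (camera adjusted p = 1.45e-07, adjusted p = 0.326 with an estimated correlation), including Ndufb10 (-0.59) and Uqcrfs1 (-0.56) of the respiratory chain. Macrophage markers were positive in 16 of 20 members with a median of 0.37 (camera adjusted p = 0.0131, adjusted p = 0.0751 with an estimated correlation). The integrin gene Itgam was 3.00 ± 3.99 (SD, n = 3) and 37.3 ± 14.7 (SD, n = 3), and the complement gene C1qa 1.67 ± 1.48 (SD, n = 3) and 22.9 ± 10.1 (SD, n = 3). In wild-type ventricular replicates 1 to 3, 1 estimated count equalled a signal of 0.941, 1.49 and 2.18. Both wild-type means therefore rest on few reads. Knockout ventricles had the higher estimated total counts in 2 of 3 pairs, and an effect of depth on such low genes was not tested. Matrix genes were positive in 37 of 55 members with a median of 0.19 (camera adjusted p = 0.0186, adjusted p = 0.507 with an estimated correlation), including Tnc (1.17), Vcan (0.77) and Fbn2 (0.54). Sarcomere genes had a median of 0.19 (camera adjusted p = 0.0244, adjusted p = 0.476 with an estimated correlation), led by the fetal or atrial isoform genes Myl4 (0.89) and Myh7 (0.86). Chaperone genes also had a median of 0.19 (camera adjusted p = 0.029, adjusted p = 0.0751 with an estimated correlation), with Sdf2l1 at 0.94, Pdia4 at 0.62 and Edem1 at -1.19 (-0.37 without ventricular knockout replicate 1). No member of these 5 lists was called by limma over all genes or adjusted over the list alone. The macrophage list was not called without ventricular knockout replicate 2 (camera adjusted p = 0.0656). The matrix list was not called without knockout replicates 2 and 3 and wild-type replicate 1 (0.0868, 0.116 and 0.145). The sarcomere list was not called without knockout replicates 1 and 3 and wild-type replicate 2 (0.0697, 0.353 and 0.135), with a median of 0.05 without knockout replicate 3 and 0.30 without knockout replicate 2. The chaperone list was not called without knockout replicate 3 and wild-type replicates 1 and 2 (0.353, 0.163 and 0.0575), and its median was 0.31 without knockout replicate 2. Mitochondrially encoded transcripts were negative in 15 of 15 members with a median of -0.29, not called by camera (adjusted p = 0.278) and called with the replicate block (adjusted p = 3.71e-07), which gave 8 lists. With the block and an estimated correlation together camera called 0 lists in ventricles, the adjusted p being 0.278 for mitochondrially encoded transcripts and 0.166 for fatty acid oxidation and for stress genes. Adjusted over the list alone, the atrial chamber list had 2 genes higher, smooth muscle and lung markers 1 each, calcium handling and ventricular chamber genes 1 on each side and ion channels 1 lower, all in lists not called. Calcium handling, glycolysis, p53, lymphocyte and interferon lists had medians, means and tests that differed in sign.

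**Figure D3:**
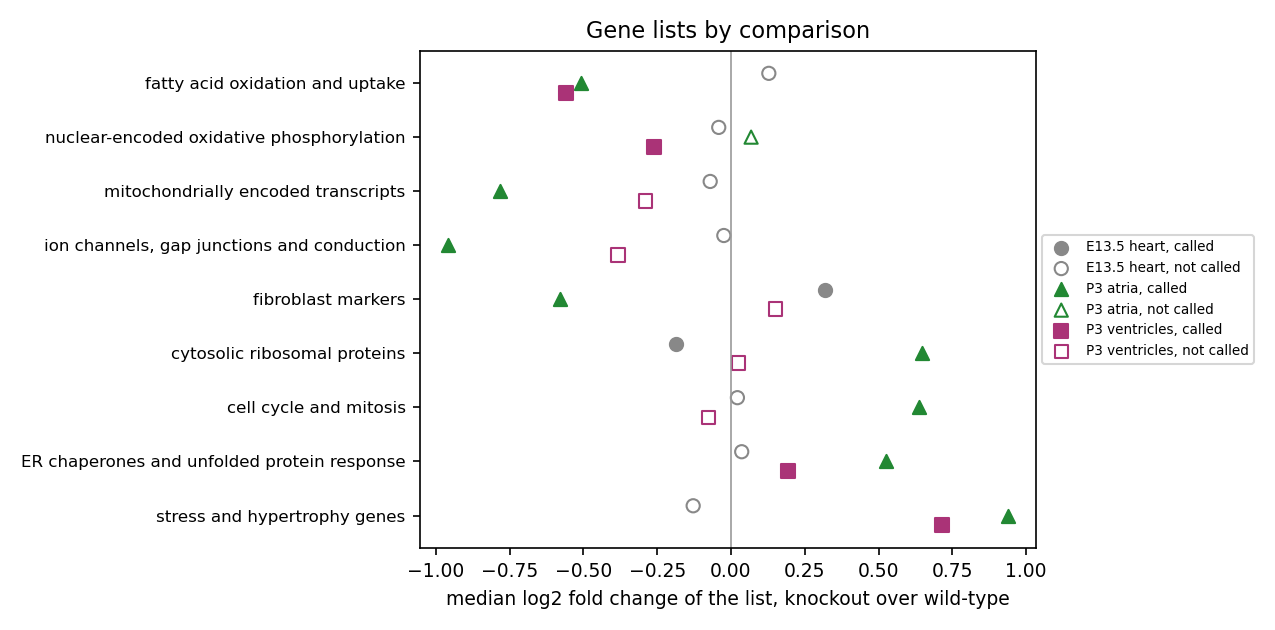
Median log2 fold change of knockout over wild-type (x axis) for 9 gene lists (y axis) in E13.5 hearts, P3 atria and P3 ventricles, with filled symbols for lists called by camera with the preset correlation. Fatty acid oxidation genes sit at -0.51 in atria and -0.56 in ventricles and at 0.13 at E13.5, and the median of oxidative phosphorylation genes in atria changed sign with the scaling.

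Mitochondrially encoded transcripts made up 39.9% ± 1.41 (SD, n = 3) of the signal in wild-type and 36.7% ± 0.523 (SD, n = 3) in knockout ventricles, lower in 3 of 3 pairs (exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 can give). In atria the shares were 24.3% ± 12.1 (SD, n = 3) and 16.8% ± 11.5 (SD, n = 3), lower in 3 of 3 pairs, and the third pair stood apart with 10.4% and 3.55%. The exact permutation test of the atrial shares (two-sided p = 0.5) ignores the pairs, so it does not test the fall within pairs. At E13.5 the share was 21.2% ± 0.707 (SD, n = 4) in wild-type and 19.5 to 22.4% over all 8 libraries, lower in knockout in 2 of 4 pairs (exact permutation test, two-sided p = 0.771). Globin transcripts were 0.200% ± 0.107 (SD, n = 3) of the signal in wild-type and 0.910% ± 0.954 (SD, n = 3) in knockout atria, higher in 3 of 3 pairs (exact permutation test, two-sided p = 0.1, the smallest possible). The knockout shares were 0.324, 0.395 and 2.01%, the highest from the third pair. The groups stayed apart only by 0.3241% in knockout replicate 1 beside 0.3236% in wild-type replicate 3.

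**Figure D4:**
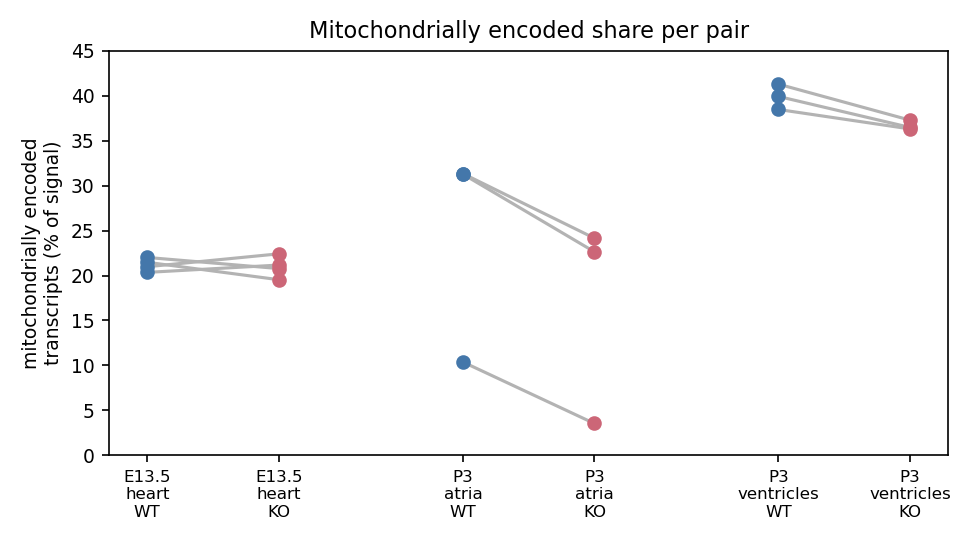
Percent of each library's signal from mitochondrially encoded transcripts (y axis) by group, with points for libraries and lines joining libraries of the same replicate number. Knockout lies below wild-type in 3 of 3 pairs in both P3 tissues, and the third atrial pair lies at 10.4% and 3.55%.

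Whether the knockout effect differed between ventricles and atria was tested on each pup's difference between its 2 libraries. For wild-type pup 2 this subtracts libraries that differed in sex-linked transcripts, so they need not come from 1 animal. Limma called 0 genes, with 469 at an unadjusted p under 0.05 and a smallest adjusted p of 1, and without that pup it called 0, with 447 at an unadjusted p under 0.05. In the 6-group fit, which ignores the pup, limma called 1 gene: Mest, with a difference of -2.50 and an SE of 0.33 (limma adjusted p = 0.00465), being 2853 ± 236 (SD, n = 3) in wild-type and 2292 ± 352 (SD, n = 3) in knockout ventricles. Camera called 10 list differences between the tissues, among them fibroblast markers (0.97), cell cycle genes (-0.76), ribosomal protein genes (-0.66) and oxidative phosphorylation genes (-0.35). None held with an estimated correlation (lowest adjusted p = 0.323). Between ventricles and E13.5 hearts limma called 0 gene differences, with 729 at an unadjusted p under 0.05, and 1 with the replicate block or without ventricular wild-type replicate 2. Camera called 5 list differences there, led by fatty acid oxidation (-0.69) and stress genes (0.85), and none held with an estimated correlation (lowest adjusted p = 0.0661). No gene was called in both P3 tissues, and 1 was called in both with the replicate block, Nppa. Both tissues came from the same pups by the labels, so their calls are not independent. Across 18125 genes, which are not independent replicates, the log2 fold changes of atria and ventricles had a Spearman rho of 0.0899, where the other 9 splits of the pups gave -0.0660 to 0.0553. E13.5 had a rho of -0.0219 with atria and 9.81e-04 with ventricles.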

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

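Chosen only after the result was seen were the tests of wild-type pup 2, of depth, litter and neighbouring tissue for the third atrial pair, and of the cardiomyocyte share, pup 2 and the third pair in atria for the shift toward E13.5.

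In E13.5 knockout hearts 4 single values stood apart from the other 3 of their group. Tprkb, a tRNA modification gene, was 6.39 in replicate 4 beside 62.5 to 69.3, and Fam192a, a proteasome-interacting protein gene, 2.39 in the same library beside 37.3 to 53.8. The ribosomal protein gene Rps27 was 3006 in replicate 2 beside 4330 to 4439, and Rps18 was 4845 in replicate 4 beside 4000 to 4119. With 46 groups of values tested, 2.3 such findings would be made by chance.

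The knockout effect differed between ventricles and atria in 10 lists by camera, as ventricular minus atrial median log2 differences. Fibroblast markers had 0.97, macrophage markers 0.70, immediate early genes 0.67, epicardial markers 0.65, cushion and valve genes 0.52 and ion channels 0.44. Cell cycle genes had -0.76, ribosomal protein genes -0.66, oxidative phosphorylation genes -0.35 and erythroid markers -1.13. Between ventricles and E13.5 hearts 5 lists differed: stress genes by 0.85, sarcomere genes by 0.21, ribosomal protein genes by 0.19, oxidative phosphorylation genes by -0.22 and fatty acid oxidation genes by -0.69. None of the 15 differences held with an estimated correlation, the lowest camera adjusted p being 0.0661.

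Wild-type pup 2 gave an atrial library with Xist at 2876 and Y-linked transcripts at 33.5, and a ventricular library with Xist at 74.9 and Y-linked transcripts at 3223. With 1 added to each level the Y-linked fold was 93.5, where the other 5 pups had at most 1.68, which argues against both libraries coming from the same animal. Over 8 genes at least 20-fold higher in the other wild-type ventricles than in the other wild-type atria, the atrial library held a median of 19.3% of the ventricular level (at most 1.58% in the other atria), Myl2 standing at 9242, so ventricular tissue in this library is a candidate source. Its Y-linked level was 0.0539 of what that share of the same-labelled ventricular library would bring, which argues against that animal as the source. Which label or tube is wrong stays open, and no biological explanation was tested.

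The third atrial pair lay apart from the other atria. Against the other 4 libraries, the 20% of genes with the lowest GC content had a median log2 difference of -0.71 and the 20% with the highest 1.56, a gap of 2.27 (-0.0071 in the ventricles of the same pups), so a bias by GC content may have shaped this pair. Depth was argued against, since 2 of 2 totals lay within the range of the other 18 libraries. Litter or preparation day stayed open by the ratio of distances to and among the other libraries, which was 1.11 in ventricles and 1.19 in atria. The 2 libraries of the pair lay 136 apart and 254 from the others in atria, but 223 and 212 in ventricles. Together with the GC gap, which was absent in ventricles, this argues against a litter offset shared by both tissues. An effect on the atria alone stays open. Neighbouring tissue stayed open: brown fat markers had 2.07 (1.60 over the tested members), with 3.46 in wild-type replicate 3 and 0 in knockout replicate 3, while lymphocyte and thymus markers had 1.57 (-0.58 over the tested members), with 1.95 and 0.89, and the rule for this verdict was extended to require both libraries after these values were seen; no biological explanation was tested.

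Genes at least 4-fold higher or lower in wild-type E13.5 hearts were chosen against wild-type ventricles for the atrial comparison and against wild-type atria for the ventricular one, and the knockout fold changes of genes higher at E13.5 lay above those of genes lower at E13.5 by 0.52 in atria (0.36, 0.88 and 0.30 in the 3 pairs) and 0.26 in ventricles (0.13, 0.02 and 0.10 in the 3 pairs). In atria the genes higher at E13.5 had a median of 0 and those lower a median of -0.52, and in ventricles the medians were 0.18 and -0.08, so that the atrial shift came from the genes lower at E13.5. Quantile scaling left at least 0.709 of the shift, and the atrial shift kept 0.735 of its size without wild-type pup 2 and 1.13 without the third pair, which argues against scaling, and in atria against that pup and that pair, as the whole cause. For a lower cardiomyocyte share 6 other cell types were read. In atria 1 of the 6 had a positive median and fibroblast markers were lower, and in ventricles 5 of 6 were positive. A lower share need not raise every other type, and erythroid markers, outside the 6, had a median of 1.34 in atria. This reading therefore cannot decide in either tissue. In ventricles 0.539 of the shift was left without the third pair, so that pair stays open there. Retained embryonic expression stays open too, since the ventricular shift of 0.262 was 0.186 under quantile scaling and 0.141 without the third pair, and in atria another of the 10 splits gave a shift of 0.65 in size, while in ventricles the real split gave the largest (highest other 0.16). In every split the genes were those chosen with the labelled wild-type pups. An effect of these pups shared by both tissues would favour the real split, so its rank does not decide.

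Other splits of the libraries were counted for each result. At E13.5 31 of 35 splits gave as many genes at an unadjusted p under 0.05 as the real 747 (highest other 893) and 11 of 35 as many lists as the real 2 (highest other 4), so chance could not be excluded for either. For the difference between ventricles and E13.5 hearts 16 of 100 drawn splits reached 729 genes (highest other 805), and chance could not be excluded. In P3 tissues 10 splits are too few for a share under 0.05. There, 5 splits reached the real 964 atrial genes (highest other 4351), 4 reached the 5 called by limma (highest other 1123), 1 reached the 17 lists (highest other 10), and 5 reached the 469 genes of the tissue difference (highest other 2369). In ventricles 1 split, the real one, reached 707 genes (highest other 673), and 1 reached 7 lists (highest other 5). The atrial split calling 1123 genes set wild-type replicates 1 and 2 with knockout replicate 2 against the rest, which points to a structure of the samples, both libraries of the third pair lying on 1 side. With the replicate block, among splits that part all pairs, the real one gave 1593 genes at an unadjusted p under 0.05 and 30 calls in atria (highest other 596 and 0), 1102 and 2 in ventricles (898 and 0), and 1167 and 0 at E13.5 (1489 and 1).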

How the results depend on the processing

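The voom weights, the fits without the third atrial pair or wild-type pup 2, the removal of mitochondrial transcripts, the replicate block with an estimated correlation and the variance trend on the mean difference were chosen only after results were seen.

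Creld1 stayed lower in knockout and uncalled in all 3 comparisons under all 117 values, with log2 fold changes of -2.30 to -1.07 at E13.5, -1.71 to -0.36 in atria and -1.26 to -0.49 in ventricles. The 15 counts of called genes and lists stayed within 1.5 times the reported count in 261 of 284 values with 1 library left out and 238 of 281 under other alternatives, and the 3 counts at an unadjusted p under 0.05 in 58 of 60 and 45 of 57. Of the values of single genes and lists, 3049 of 3140 with 1 library left out kept their direction and call, 82 lost a call, 2 gained one and 7 changed direction, and under other alternatives 2826 of 2974 kept both, 122 lost a call and 26 gained one. Lost calls could come only from the 5 called genes and from the called lists, 2 at E13.5, 17 in atria and 7 in ventricles. Most of the 157 genes and lists were uncalled in the main fit and could lose none, so these shares overstate how stable the calls were. Mest was called under 38 of 39 alternatives, Nppb under 36, Lum under 33, Casq1 under 30 and Birc5 under 20, with limma adjusted p of 1.54e-05 to 1 for Mest and 7.31e-04 to 0.946 for Nppb. The cell cycle, ion channel, chaperone and fibroblast lists in atria were called under all 39 alternatives run on them. The fatty acid oxidation lists in atria and ventricles and the stress list in ventricles were called under 38, and not with the replicate block and an estimated correlation together (camera adjusted p of 0.146, 0.166 and 0.166).

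The replicate block gave 20 genes higher and 10 lower in atria, 2 higher in ventricles (adjusted p of Nppa 0.00121, and 7.54e-04 to 1 over its alternatives), 1 differing between ventricles and E13.5 hearts and 1 called in both P3 tissues. Its list calls were 18 in atria and 8 in ventricles. Among the list members named above, it also called Hba-a1, Hsp90aa1, mt-Nd4l and Postn in atria (limma adjusted p = 0.0425, 0.0425, 0.0425 and 0.0447). Genes at an unadjusted p under 0.05 were 1167 at E13.5, 1593 in atria and 1102 in ventricles with it, 1600 in atria and 1068 in ventricles with the litter block, 572 and 1065 with separate fits, and 1851 and 1144 with arrayWeights. At E13.5 they were 1149 with no filter and 473 with the stricter one, and with the stricter one 424 in ventricles. The litter block gave 20 higher and 14 lower in atria, 2 higher in ventricles, 1 between ventricles and E13.5 hearts and 1 shared. Separate fits, in which the libraries of 1 stage and tissue alone set the spread, gave 0 higher and 0 lower in atria. They lowered the atrial count at an unadjusted p under 0.05 from 964 to 572 and raised the ventricular one from 707 to 1065. Library weights (arrayWeights) gave 14 higher and 14 lower in atria, and 5 higher and 1 lower in ventricles. The Xist covariate left 2 higher and 0 lower in atria, and leaving out wild-type pup 2 left 2 and 0, in both cases Mest and Nppb, with 1 higher in ventricles, 1 between ventricles and E13.5 hearts and 11 atrial lists. Without the third atrial pair 7 genes were lower in atria and 1 higher in ventricles. A pseudocount of 0.1 gave 2 lower in atria and 3 higher in ventricles, and no filter 2 lower in atria and 2 lower in ventricles. A threshold of 0.1 and the stricter filter of 50 each gave 2 lower in atria and kept all 5 calls. Voom weights also gave 2 lower but kept 3 of the 5 calls, losing Casq1 and Birc5. An estimated correlation left 0 lists at E13.5, 5 in atria and 2 in ventricles, and fry 0, 6 and 2. With the replicate block and an estimated correlation together camera called 0 lists at E13.5, 6 in atria and 0 in ventricles. The 6-group fit without the pup gave 1 gene differing between ventricles and atria, and the variance trend on the mean difference 0 chamber genes. None of the causes of these changes was tested.

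Leaving out 1 library at a time gave 17 to 26 chamber genes, 1 to 3 lists at E13.5 and 10 to 19 in atria. At E13.5 it gave 0 to 1 genes higher (1 without wild-type replicate 3) and 0 to 1 lower (1 without wild-type replicate 4). In atria it gave 1 to 11 higher and 0 to 5 lower, the most without wild-type replicate 3. In ventricles it gave 0 to 1 higher and 0 to 1 lower, and 0 to 1 genes differing between ventricles and E13.5 hearts. Of 134 fold changes of named genes 51 moved by over 1.5 times and 21 by over 2 times. Among single lists and genes, only atrial ones changed direction. Without knockout replicate 3 the medians were -0.11 for ATF4 genes, -0.24 for glycolysis, -0.18 for hypoxia and 0.28 for mitochondrially encoded transcripts, with mt-Atp6 at 0.22 and mt-Nd1 at 0.0738, and without wild-type replicate 1 the hypoxia median was -0.00464. Over all libraries left out these ranged from -0.11 to 0.66 for ATF4 genes, -0.24 to 0.63 for glycolysis, -0.18 to 0.41 for hypoxia -1.53 to 0.28 for mitochondrially encoded transcripts, -2.10 to 0.22 for mt-Atp6 and -1.48 to 0.0738 for mt-Nd1. Without knockout replicate 3 its partner of the third pair stayed in the wild-type group alone. That pair's median log2 difference from the other atria was -2.68 for mitochondrially encoded transcripts and 1.45 for glycolysis. It was 1.08 for ATF4 and 0.82 for hypoxia genes. The changes of direction without knockout replicate 3 thus went the way this offset moves the wild-type mean. Other causes were not tested. Leaving out a library leaves some groups with few libraries, whose spread is assumed to be that of the other groups.

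The planned count-model alternative was not run, because only 45.2 to 64.6% of values came out as whole reads. Depth was 5138352 to 20669361 estimated counts. With it the simulated 2-fold changes, all in genes of at least median level, were recovered in 11.9 to 35.8% of these genes. The low counts of calls thus do not exclude changes of that size.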

Other observations

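The values here were chosen for description only after results were seen, and levels were not tested between E13.5 and P3.

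Mest and Birc5, which rose in knockout atria, were both abundant in E13.5 hearts. Mest stood at 11298 ± 1169 (SD, n = 4) in wild-type and 10113 ± 1638 (SD, n = 4) in knockout hearts at E13.5, beside 2572 ± 378 (SD, n = 3) in wild-type and 11702 ± 2064 (SD, n = 3) in knockout atria at P3. Birc5 stood at 1318 ± 152 (SD, n = 4) and 1142 ± 198 (SD, n = 4) at E13.5, beside 245 ± 21.7 (SD, n = 3) and 708 ± 168 (SD, n = 3) in atria. In ventricles Birc5 was 728 ± 106 (SD, n = 3) in wild-type and 696 ± 149 (SD, n = 3) in knockout.

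Casq1 was 96.1 ± 36.1 (SD, n = 3) in wild-type and 692 ± 567 (SD, n = 3) in knockout ventricles, higher in 3 of 3 pairs and not called (limma adjusted p = 0.571). At E13.5 it was 579 ± 202 (SD, n = 4) and 499 ± 66.9 (SD, n = 4). Nppb at E13.5 was 614 ± 207 (SD, n = 4) in wild-type and 474 ± 117 (SD, n = 4) in knockout hearts. Mb, which encodes myoglobin, was 14799 ± 1230 (SD, n = 3) in wild-type and 8258 ± 92.8 (SD, n = 3) in knockout ventricles, lower in 3 of 3 pairs, with a limma adjusted p of 1. Lum was 2094 ± 293 (SD, n = 3) in wild-type and 1605 ± 272 (SD, n = 3) in knockout ventricles.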
